A study of Caenorhabditis elegans with 11 samples.

How the data were processed

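The series measured where RNA polymerase II (Pol II) and histone H3 trimethylated at lysine 9 (H3K9me3) sit on the genome of the nematode Caenorhabditis elegans, by chromatin immunoprecipitation and sequencing (ChIP-seq) of young adult hermaphrodites. It holds 11 samples: 8 Pol II libraries, 1 for each combination of 3 genotype factors, and 3 H3K9me3 libraries. The factors were loss of hrde-1, loss of set-32, and joint loss of met-2 and set-25, and the wild-type strain was N2. HRDE-1 is a germline Argonaute protein of nuclear RNA interference, MET-2 and SET-25 are histone H3 lysine 9 methyltransferases, and SET-32 is a protein of the same SET domain class. The values analysed are the 8 Pol II libraries. The 3 H3K9me3 libraries were not analysed here, and the comparisons planned for them, including those at oma-1, were not run.

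The deposited table gives RPKM values, made by the authors, in 100257 genome bins of 1 kb. RPKM counts reads relative to the length of a bin and to all reads of the library, so in bins of equal length it is a share of the library's reads. The values of a library summed to between 995904 and 998698. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The genome build, the treatment of reads that map to several places and any filter are not given in the sources used here. Positions below are those of the deposited table, in which chromosome V ends at 20920 kb. The gene positions at hand belong to another coordinate set, so regions are named by position, no gene is assigned to them, and the planned gene lists and the check of the mutated genes were not run. The table has 43 library columns. A column was used only where its name matched the label of 1 sample of the series, which left 35 columns unused.

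The deposited table also carries 3 yes-or-no marks per bin, set by the authors: GRTS (191 bins), GRH (215 bins, 25 of them also GRTS) and misanotated (506 bins, spelled as in the table). In the field GRTS and GRH have been used for regions with transcriptional silencing and with heterochromatin that depend on germline nuclear RNAi. How the marks were set is not given in the sources used here, and they may rest on libraries of this kind, so counts of marked bins are not independent evidence of a direction.

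Depth was estimated from the values. Low values fell on steps of 1 read: of the values up to 8 RPKM, 82.9 to 84.4% per library lay within 0.1 read of a whole number, and the rest were fractions of a read. From the step size the libraries held 3.0 to 6.60 M reads. A bin at 10 RPKM then rested on 30.0 to 66.0 reads, a counting error of 12.3 to 18.2%. Because of the fractions, whole reads were not recovered and no count model was used. No pair of libraries held identical values, and the correlation of log2 values across bins lay between 0.818 and 0.949.

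The design was fixed before the data were examined. Each factor was tested per bin with limma (version 3.58.1, R 4.3.3), moderated with an intensity trend, on log2(RPKM + 1), in an additive model of the 3 factors over the 8 libraries (4 residual degrees of freedom). Each factor thus compared 4 mutant with 4 other libraries. Bins with a mean of at least 2 RPKM were tested, tests were two-sided, and p-values were Benjamini-Hochberg adjusted with a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low bins. Neighbouring bins of the same direction, with at most 1 bin between them, were merged into regions. Values of a region are means over its bins past the threshold, the SE is the mean of their SEs, and the p given for a region is the smallest adjusted p among its bins, since regions were not tested as units. Under an alternative a region stays past the threshold if at least 1 of these bins does. Interactions were tested by adding 1 product term at a time (3 residual degrees of freedom). No genotype had a replicate, so the error is the spread of libraries around the additive model, which includes interactions, and the labels do not say how many cultures it covers.

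Each mutant was compared with N2 by a rule of size without a test: a log2 difference of at least 1 and at least 10 RPKM in the higher library. Medians of marked bins, and of autosome arms minus centres, were compared with exact two-sided permutation tests of 4 against 4 libraries (70 assignments, smallest possible p 0.0286), Benjamini-Hochberg adjusted over the 2 lists of a factor or over the 3 factors. Each autosome was divided into 3 parts of equal length, the outer parts as arms and the middle part as centre. Lists of bins defined in a pair of libraries were read in other libraries, using Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. They were set against 10000 random lists matched on the mean level of all 8 libraries. Under the alternatives the lists were defined anew, and random lists were drawn again after the data were seen. The tests on GRTS and GRH bins were added after the marks were seen. For set-32 and met-2 set-25 they were repeated with libraries exchanged only within hrde-1 status (36 assignments, smallest possible p 0.0556).

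The regions named were, by rule, those with the largest mean log2 change among regions past the threshold: up to 15 higher and 10 lower for hrde-1, and 10 and 10 for met-2 set-25. For set-32, with fewer than 5 regions past it, they were the 5 highest and 5 lowest bins by the moderated statistic. For each mutant against N2 they were the 3 highest and 3 lowest regions by the rule of size. Regions outside this rule are said to be so where they appear.

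The library codes in the labels share 3 prefixes whose meaning is not stated. N2, met-2 set-25 and met-2 set-25 hrde-1 have one, hrde-1, set-32, set-32 hrde-1 and set-32 met-2 set-25 hrde-1 another, and set-32 met-2 set-25 stands alone. The alternatives tried were pseudocounts of 0.5 and 5 RPKM, no filter or a mean of at least 5 RPKM, centring of each library on its median, quantile normalization, the prefix as a model term (2 residual degrees of freedom), each library left out in turn, other size limits, and other arm limits. After the data were seen, 2 more were added: leaving out both libraries that carry set-32, met-2 and set-25, and leaving out the misanotated bins.

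The limma step was tested on simulated data with 100 bins planted per fold size among 100027. It recovered 45% of 2-fold and 95% of 4-fold changes for hrde-1, 31% and 95% for set-32, and 43% and 97% for met-2 set-25, with 12, 14 and 10 false calls. The simulated noise was independent between bins and alike in all libraries, without interactions or differences in how evenly reads were spread. Recovery and false calls in the real libraries may therefore be worse.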

Results

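Pol II occupancy was profiled by ChIP-seq in young adult hermaphrodites of 8 genotypes, 1 library each: N2, hrde-1, set-32, met-2 set-25, set-32 met-2 set-25, set-32 hrde-1, met-2 set-25 hrde-1 and set-32 met-2 set-25 hrde-1. Together they form the complete set of combinations of the 3 factors, so each factor was present in 4 libraries and absent in 4. The title of the series concerns SET-32 in silencing by nuclear RNAi, a pathway in which small RNAs direct transcriptional repression of their targets. The estimated depth was 3.70 M reads in N2, 5.72 in hrde-1, 3.04 in set-32, 3.0 in met-2 set-25, 6.06 in set-32 met-2 set-25, 6.06 in set-32 hrde-1, 6.60 in met-2 set-25 hrde-1 and 3.07 in set-32 met-2 set-25 hrde-1. The libraries differed in how evenly the reads were spread. In set-32 met-2 set-25 and set-32 met-2 set-25 hrde-1, the ratio of the 90th to the 10th percentile over bins was 3.72 and 4.31, against 7.63 in met-2 set-25, 12.01 in N2, 12.21 in met-2 set-25 hrde-1, 14.1 in hrde-1, 14.5 in set-32 hrde-1 and 24.96 in set-32. The tenth of bins with the most Pol II held 30.0% and 30.7% of the signal in those 2 libraries and 37.2 to 47.1% in the others.

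Loss of HRDE-1 was accompanied by higher Pol II over discrete stretches of the genome on all 6 chromosomes. Among 100027 bins tested, 852 rose and 80 fell with hrde-1 loss (limma, Benjamini-Hochberg adjusted). These formed 233 higher and 45 lower regions. The change was large: 717 of the higher bins changed at least 2-fold and 220 at least 4-fold, with a median log2 change of 1.44. The median change of all bins was -0.04.

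The region with the largest change lay on chromosome IV from 912001 to 923000, where Pol II was 74.7 ± 47.4 RPKM in the 4 hrde-1 mutant libraries and 4.84 ± 1.78 RPKM in the others (SD, n = 4 each; log2 change 3.10 ± 0.30 SE, smallest limma adjusted p of its bins 1.29e-09). Here and below, the p given for a region is that of its bin with the smallest p. Within that group the hrde-1 library read 12.7 RPKM and the other 3 read 69.1 to 125 RPKM. A 15 kb region of chromosome IV, 4123001 to 4138000, held the bin with the smallest p: 94.1 ± 18.2 against 8.38 ± 1.77 RPKM (SD, n = 4; log2 change 3.10 ± 0.23 SE, limma adjusted p = 2.6e-12). On chromosome V, 17568001 to 17575000 rose from 3.83 ± 1.41 to 40.7 ± 8.39 RPKM, and on chromosome IV, 14415001 to 14417000 rose from 3.72 ± 2.22 to 39.7 ± 13.04 RPKM. Chromosome II rose between 2148001 and 2165000, from 5.61 ± 1.86 to 50.6 ± 16.5 RPKM. The longest region spanned 25 kb of chromosome V, 5180001 to 5205000, at 48.6 ± 20.1 against 6.35 ± 0.87 RPKM. A pair of 22 kb regions of chromosome V, 8825001 to 8847000 and 8867001 to 8889000, gave nearly equal values in every library (51.8 ± 17.8 and 51.7 ± 17.8 RPKM in the mutants). Of their values, 23.9% and 23.3% lay within 0.1 of a whole number of reads, against 80.1% elsewhere at 10 to 60 RPKM, so reads may be shared and their separate changes are uncertain. The other higher regions named by the rule had log2 changes of 2.35 to 2.60. They were II 10123001 to 10125000, II 10935001 to 10942000, II 13244001 to 13251000, IV 525001 to 529000, IV 16315001 to 16319000, I 4456001 to 4466000 and V 20295001 to 20307000. The 15 named higher regions stayed past the threshold under every alternative run for this effect.

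**Figure D1:**
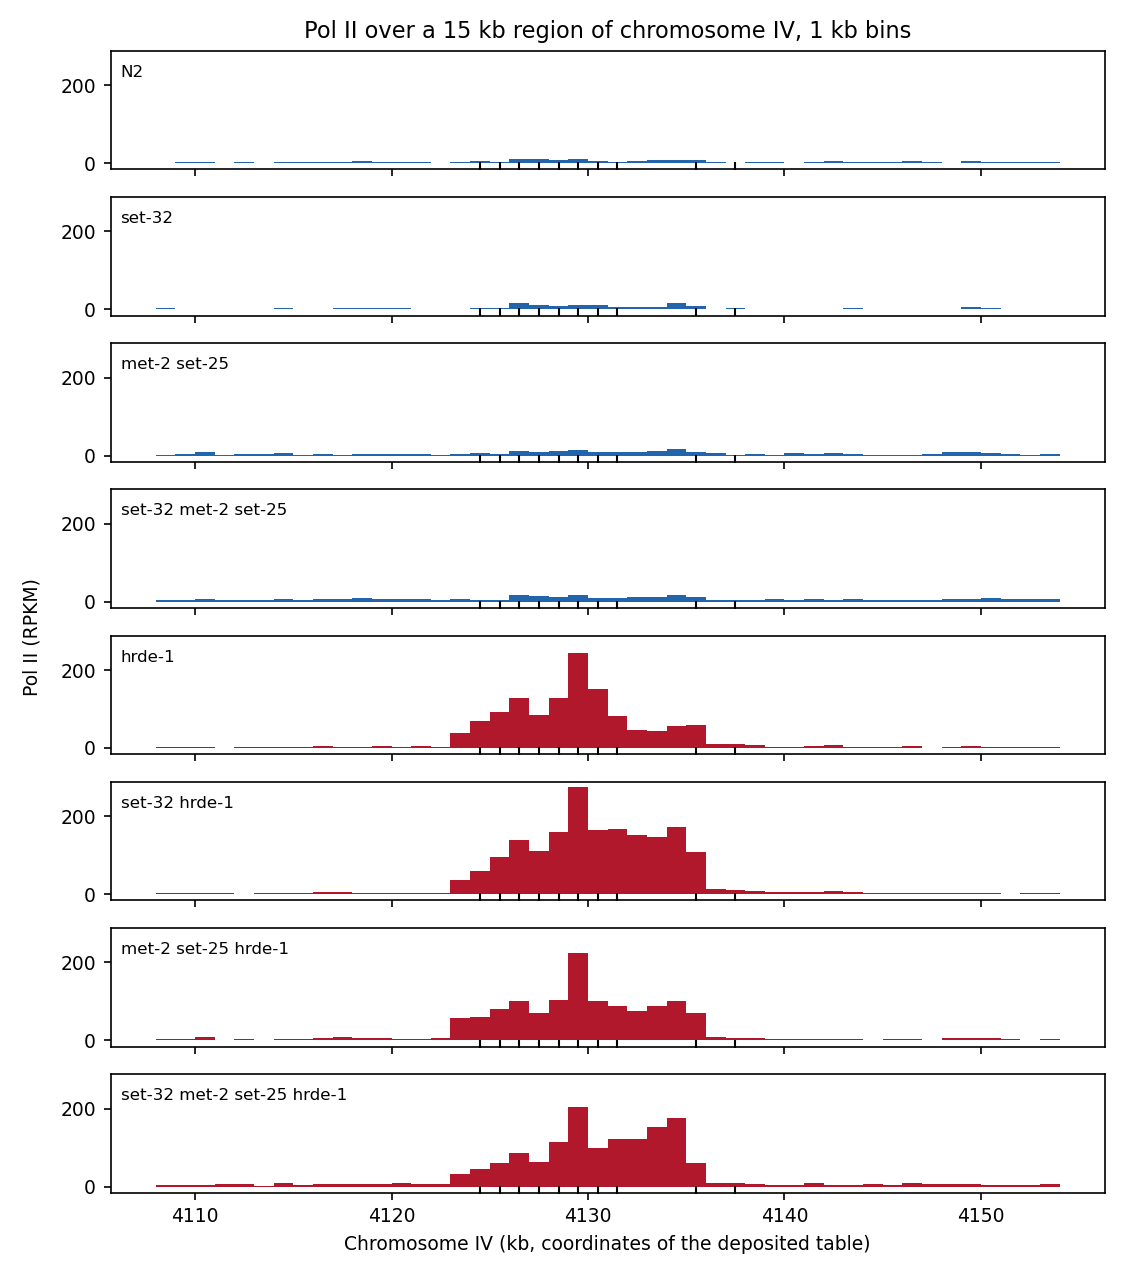
Pol II in RPKM per 1 kb bin along chromosome IV around the region from 4123001 to 4138000, 1 panel per library, all on 1 linear scale, with black ticks at bins marked GRTS. The 4 hrde-1 mutant libraries (red) average 94.1 RPKM over the region and the 4 others (blue) 8.38 RPKM.

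Bins marked GRTS were nearly all among those that rose: 187 of 191 (97.9%), against 0.852% of all bins tested, and 0 fell. Of the bins marked GRH, 97 of 215 rose and 0 fell. Because the marks may rest on such libraries, these counts and the medians that follow are not independent evidence. In the list itself, the median GRTS bin stood at 41.8 ± 12.23 RPKM in the 4 hrde-1 mutant libraries and 5.76 ± 1.60 RPKM in the others (SD, n = 4; log2 difference 2.65, exact permutation p = 0.0286, adjusted 0.0286, the smallest this design allows). The median GRH bin stood at 24.3 ± 4.27 against 12.8 ± 2.48 RPKM (log2 difference 0.87, exact p = 0.0286, adjusted 0.0286). The adjusted p rose to 0.0571 for GRTS and 0.0857 for GRH when libraries were centred, at differences of 2.72 and 0.94. Leaving out N2, met-2 set-25 or set-32 met-2 set-25 raised it to 0.0571, at differences of 2.65, 2.65 and 2.79 for GRTS and 0.90, 0.75 and 0.88 for GRH. Of the 4 GRTS bins that did not pass, 3 were higher by 0.87 to 0.97 on the log2 scale (I 11441001, IV 12507001 and V 1587001, limma adjusted p = 0.27, 0.0627 and 0.0715) and V 16102001 was at -0.27.

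**Figure D2:**
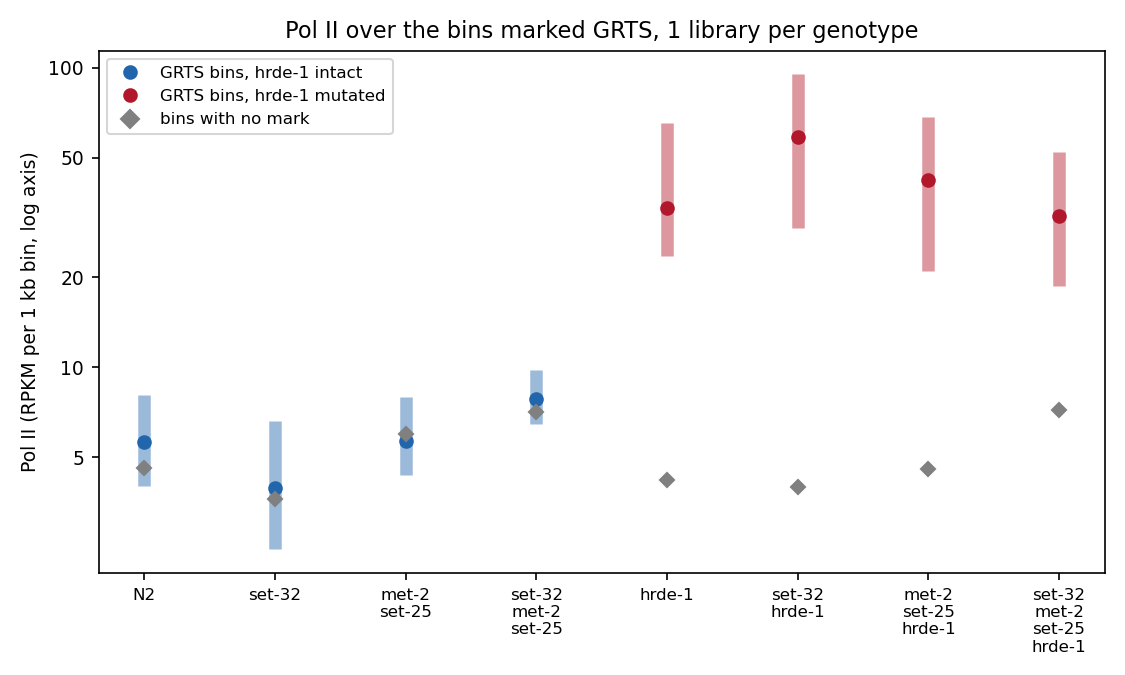
Median Pol II (points, RPKM per 1 kb bin, log axis) over the 191 bins marked GRTS in each library, with bars from the 25th to the 75th percentile over bins and grey diamonds for the median of bins with no mark. The hrde-1 mutant libraries lie between 32.1 and 58.9 RPKM and the others between 3.95 and 7.84 RPKM.

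The rise extended beyond the marked bins. Besides the 187 GRTS bins, 242 higher bins lay within 5 kb of a GRTS bin and 423 farther away. Thus 50.4% of the higher bins were GRTS bins or within 5 kb of one, against 0.885% of all bins tested. Regions with a GRTS bin numbered 62 and had a median length of 4.5 kb, and the regions without one had a median of 2 kb. Neither a GRTS nor a GRH bin lay in 147 regions, among them II 10123001 to 10125000, where Pol II was 26.8 ± 15.2 RPKM in the mutants and 2.78 ± 1.40 RPKM in the others (log2 change 2.60 ± 0.27 SE). Chromosome V held 303 higher bins, II 161, I 150, IV 149, III 75 and X 14.

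**Figure D3:**
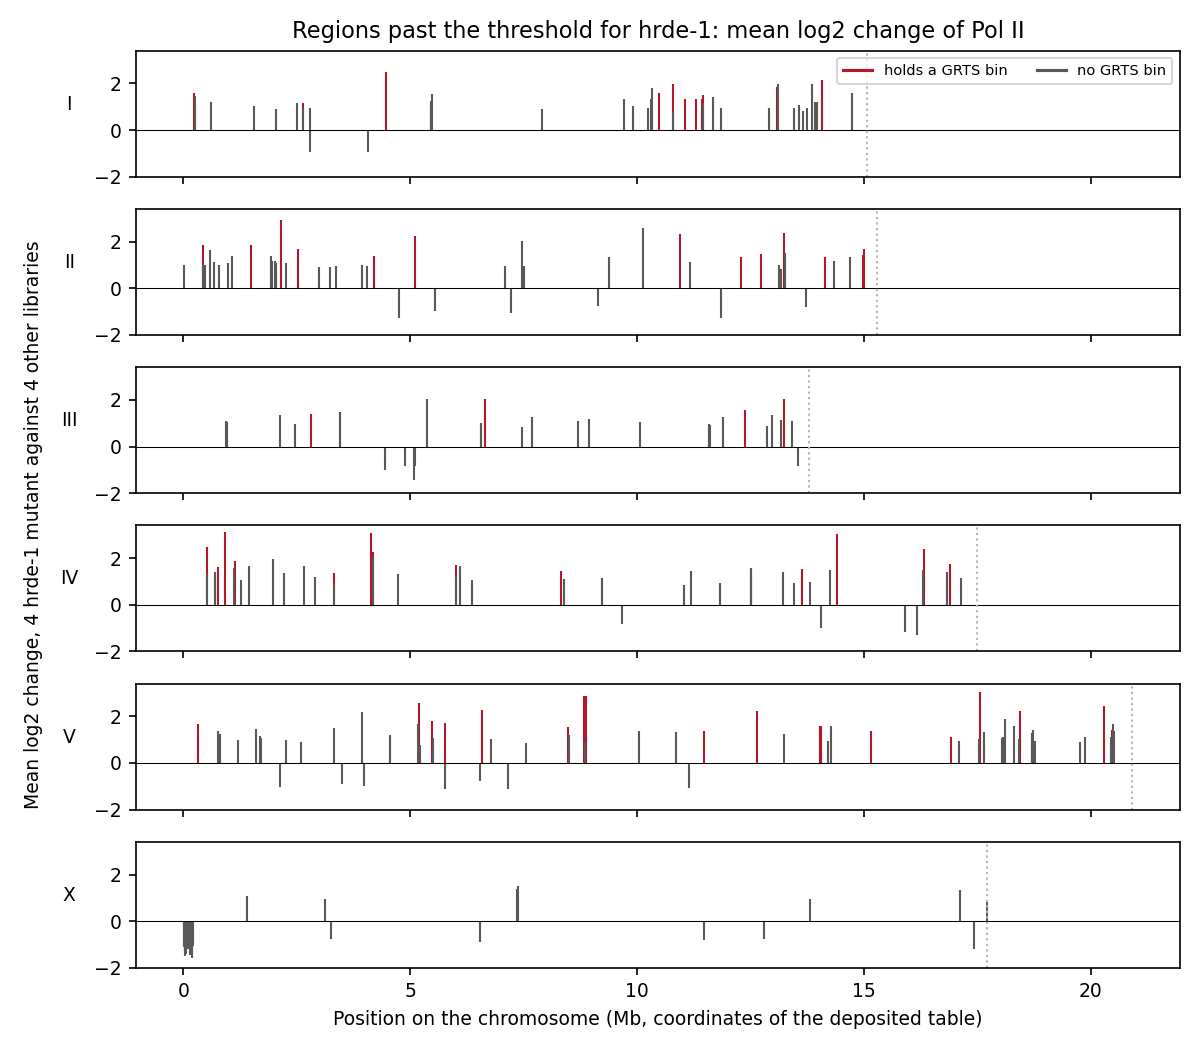
Mean log2 change of Pol II with hrde-1 loss (vertical axis) for each region past the threshold along the 6 chromosomes (Mb), red where the region holds a GRTS bin. Higher regions occur on every chromosome, with 7 on X, and lower regions crowd at the left end of X.

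Lower Pol II with hrde-1 loss was centred on the X chromosome, which held 50 of the 80 lower bins, most of them near its left end. X 192001 to 194000 fell by 1.60 on the log2 scale (7.73 ± 10.5 against 16.5 ± 5.63 RPKM, SD, n = 4; limma adjusted p = 0.00108) and X 150001 to 159000 fell by 1.45 (9.998 ± 9.78 against 23.4 ± 8.73 RPKM, limma adjusted p = 7.55e-05). X 35001 to 36000, X 48001 to 53000, X 32001 to 33000 and X 181001 to 182000 fell by 1.47, 1.41, 1.36 and 1.31. The mutant libraries differed here: over X 150001 to 159000 the set-32 hrde-1 library read 24.4 RPKM, near the 28.8 RPKM of N2, while hrde-1, met-2 set-25 hrde-1 and set-32 met-2 set-25 hrde-1 read 6.95, 5.69 and 2.90 RPKM. Elsewhere III 5092001 to 5093000, IV 16171001 to 16173000, II 4748001 to 4751000 and II 11843001 to 11844000 fell by 1.42, 1.30, 1.27 and 1.27. There set-32, with intact hrde-1, also read low, at 15.5, 22.95, 9.1 and 7.91 RPKM (N2 65.4, 69.2, 27.35 and 36.7). It shares its prefix with 3 of the 4 hrde-1 mutants. The other, met-2 set-25 hrde-1, read 29.4, 17.9, 4.7 and 11.7 RPKM. Of the 10 named lower regions, 1 stayed past the threshold with the prefix as a term and 4 after quantile normalization. The count of lower bins was unstable, at 38 when libraries were centred, 15 after quantile normalization, 34 with the prefix as a term and 16 at a mean of at least 5 RPKM. It was 23 without hrde-1, 49 without met-2 set-25, 44 without set-32 met-2 set-25, 222 without set-32 hrde-1, 323 without set-32 met-2 set-25 hrde-1 and 435 without set-32.

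**Figure D4:**
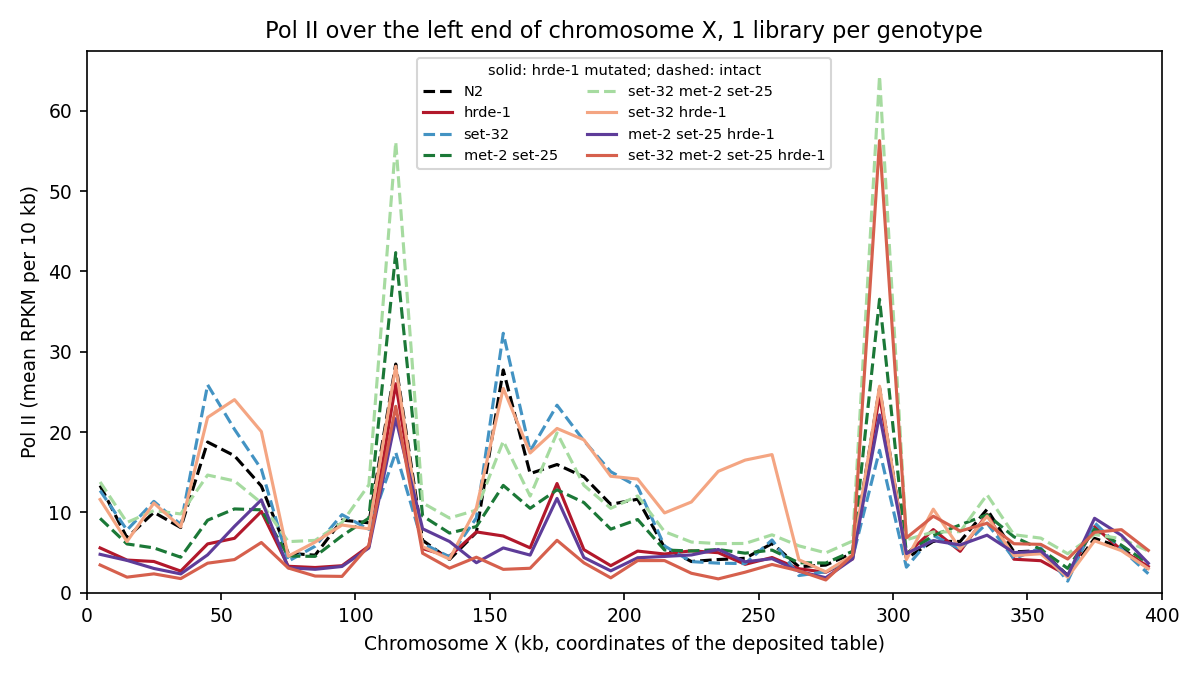
Pol II along the left end of chromosome X (kb) in each library (mean RPKM per 10 kb), solid lines for hrde-1 mutants and dashed lines for strains with intact hrde-1. Over the first 210 kb hrde-1, met-2 set-25 hrde-1 and set-32 met-2 set-25 hrde-1 average 6.63, 6.07 and 4.52 RPKM and the other libraries 10.2 to 13.9 RPKM.

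Loss of SET-32 gave almost no call. By limma, 0 bins rose and 1 fell, while 4133 bins had an unadjusted p under 0.05. The bin that fell, II 504001 to 505000, carries the misanotated mark and read 9.53 ± 4.71 RPKM in the set-32 mutant libraries and 101 ± 89.2 RPKM in the others (SD, n = 4; log2 change -2.81 ± 0.41 SE, limma adjusted p = 0.0261). It did not pass with a pseudocount of 0.5 RPKM, at a mean of at least 5 RPKM or after quantile normalization, and its log2 change was -0.37 with the prefix as a term and -1.34 without both evenly covered libraries. Without set-32 met-2 set-25 or met-2 set-25 hrde-1 it was -2.55 and -2.20 and did not pass (limma adjusted p = 0.128 and 0.355). The next bins by rule did not pass. V 796001 to 797000 read 23.4 ± 18.2 against 7.14 ± 4.58 RPKM, IV 16316001 to 16317000 read 40.9 ± 43.9 against 10.2 ± 7.51 RPKM and V 18122001 to 18123000 read 37.8 ± 39.3 against 9.21 ± 7.08 RPKM. Toward lower values, III 10987001 to 10988000 read 5.41 ± 3.26 against 17.2 ± 12.99 RPKM and X 421001 to 422000 read 4.98 ± 1.27 against 16.9 ± 10.96 RPKM. Adjusted p over these 5 bins ran from 0.0552 to 0.288 (limma). The count depended on the libraries: without set-32 it was 37 higher and 10 lower, without set-32 hrde-1 8 and 57, without hrde-1 3 and 40, without N2 26 and 5, and without set-32 met-2 set-25 hrde-1 8 and 12. Without met-2 set-25 it was 4 and 3, and without set-32 met-2 set-25 or met-2 set-25 hrde-1 0 bins fell. With the prefix as a term it was 28 and 2.

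Over the GRTS bins, 0 of 191 passed for set-32 in either direction by limma. Their median differed by 0.10 on the log2 scale between set-32 mutant and other libraries (exact permutation p = 0.886, adjusted 0.914, n = 4), turning to -0.0011 when libraries were centred. GRH bins differed by 0.04 (exact p = 0.914), turning to -0.06 when centred. This permutation says little, because each arm mixes hrde-1 mutant and intact libraries (SD 1.66 and 1.48 for GRTS), and in simulation with such a hrde-1 difference it recovered 0% of planted 2-fold changes. With libraries exchanged only among those of equal hrde-1 status, a test added after the data were seen, exact permutation p was 0.778 for GRTS and 0.833 for GRH (36 assignments, smallest possible p 0.0556). Pair by pair, the median GRTS difference with set-32 loss was -0.26 in the N2 background, 0.39 in met-2 set-25, 0.27 in hrde-1 (libraries of 1 prefix) and -0.24 in met-2 set-25 hrde-1. Centred, these were 0.013, 0.18, 0.34 and -0.76. The design cannot exclude small effects here: by limma, planted 2-fold changes were recovered in 31% of simulated bins. That simulation held noise alike in all libraries, so recovery in the real ones may be lower.

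Joint loss of MET-2 and SET-25 gave 318 higher and 127 lower bins in 196 and 93 regions (limma, Benjamini-Hochberg adjusted), while the median of all bins moved by 0.40. IV 5682001 to 5690000 stood at 11.6 ± 0.28 RPKM in the 4 mutant libraries and 2.63 ± 0.38 RPKM in the others (SD, n = 4; log2 change 1.79 ± 0.25 SE, limma adjusted p = 2.7e-06). II 4171001 to 4174000 rose from 2.63 ± 1.03 to 14.2 ± 5.11 RPKM. V 20501001 to 20505000 stood at 63.3 ± 62.6 against 10.8 ± 6.71 RPKM (limma adjusted p = 0.000128), with 149 RPKM in set-32 met-2 set-25 hrde-1, 69.9 in met-2 set-25 hrde-1, 18.4 in set-32 met-2 set-25, 15.6 in met-2 set-25 and 20.8 in set-32 hrde-1. A 17 kb region of chromosome I, 10203001 to 10220000, rose from 11.8 ± 2.36 to 44.2 ± 14.3 RPKM, and 16 of its bins carry the misanotated mark. V 20509001 to 20511000 and III 13019001 to 13020000 rose by 1.72 and 1.65 on the log2 scale. Single bins at I 4161001, V 2529001, IV 1825001 and IV 15860001 rose from means of 1.20 to 1.58 RPKM to means of 6.41 to 7.14 RPKM.

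Lowest with met-2 set-25 loss were a pair of short regions of chromosome III, the chromosome that carries both genes. III 13287001 to 13289000 fell by 3.10 on the log2 scale (2.22 ± 0.64 against 19.1 ± 1.40 RPKM, SD, n = 4; limma adjusted p = 7.93e-09). III 8376001 to 8378000 fell by 2.11 (7.04 ± 1.06 against 31.0 ± 4.63 RPKM, limma adjusted p = 4.36e-08). Within them the bin III 13288001 to 13289000 read 0.00 to 0.17 RPKM in the 4 carriers and 16.8 to 19.99 RPKM in the others. Bins at 0 RPKM were rare, at 12, 3, 6 and 5 of 100257 in met-2 set-25, set-32 met-2 set-25, met-2 set-25 hrde-1 and set-32 met-2 set-25 hrde-1. DNA missing from the carriers would give such values, so these falls are not evidence of lower Pol II. Whether the DNA of these regions is present in the carriers was not tested. A search over all bins, with limits chosen after the data were seen, asked for at most 35% of the lowest non-carrier in every carrier. It found 3 such bins for met-2 set-25, all in these regions, 0 for hrde-1 and 0 for set-32. In the reverse direction, with the non-carriers low, it found 9 bins for met-2 set-25, 114 for hrde-1 and 0 for set-32. The other named lower regions had log2 changes of -1.46 to -1.31: II 2273001 to 2274000, II 10935001 to 10936000, IV 10355001 to 10356000, V 1205001 to 1207000, I 4467001 to 4468000, X 48001 to 50000, X 192001 to 193000 and X 153001 to 161000. The 3 on X lie in the left-end stretch named above for hrde-1, and there the hrde-1 library, with intact met-2 and set-25, read 4.37, 3.93 and 7.24 RPKM, below the 9.74, 10.98 and 13.6 RPKM of met-2 set-25.

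With met-2 set-25 loss, 1 of 191 GRTS bins rose and 0 fell by limma. Their median differed by 0.07 on the log2 scale (exact permutation p = 0.971, n = 4), turning to -0.42 when libraries were centred, and exact p was 0.944 as reported and 0.333 centred when libraries were exchanged only within hrde-1 status. Pair by pair, the GRTS difference was 0.09 in the N2 background (libraries of 1 prefix), -0.03 in hrde-1, 0.81 in set-32 and -0.87 in set-32 hrde-1 (libraries of 1 prefix). Centred, these were -0.24, -0.16, 0.0033 and -1.59. GRH bins were at -0.34 (exact p = 0.429, adjusted 0.857) with 8 of 215 lower by limma, at -0.84 when centred (adjusted exact p = 0.229) and at -0.15 after quantile normalization (adjusted exact p = 1). Within hrde-1 status the exact permutation p was 0.0556 both as reported and centred, the smallest these 36 assignments allow (adjusted 0.111). The GRH difference was negative in all 4 pairs, at -0.30 in N2, -0.07 in hrde-1, -0.27 in set-32 and -0.45 in set-32 hrde-1 (-0.62, -0.21, -1.08 and -1.17 centred). Its size depends on the scaling. GRH bins stood above bins with no mark in N2 (medians 13.4 and 4.59 RPKM). Even coverage, in met-2 set-25 and the 2 evenly covered libraries, may thus pull them down, which was not tested. In the hrde-1 background 90 of 215 bins were higher. That pair is not free of this limit, since met-2 set-25 hrde-1 was more even than hrde-1 (ratios of the 90th to the 10th percentile 12.21 and 14.1). A lower level at GRH bins is left open. Of the 502 misanotated bins tested, 38 rose and 1 fell. Their median moved with the evenness of the libraries: it was 31.9 and 32.7 RPKM in the 2 evenly covered libraries, 23.0 in met-2 set-25, 13.4 in met-2 set-25 hrde-1 and 15.8 in N2.

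The met-2 set-25 counts rest on both evenly covered libraries, which carry this genotype together with set-32. Without them 19 bins rose and 7 fell, with 6221 at an unadjusted p under 0.05, and a median shift of 0.10. Centring gave 446 higher and 6828 lower bins, and quantile normalization 41 and 6. With the prefix as a term 64 rose and 78 fell. Leaving out 1 library gave 31040 higher and 7479 lower bins without met-2 set-25 hrde-1, 4875 and 1909 without N2, 77 and 30 without set-32 met-2 set-25, 142 and 61 without hrde-1, 167 and 47 without set-32, 186 and 45 without met-2 set-25, 524 higher without set-32 hrde-1, and 72 lower without set-32 met-2 set-25 hrde-1. Of the 20 named regions, 6 stayed past the threshold without both evenly covered libraries: III 13287001, III 8376001, IV 5682001, V 20501001, V 20509001 and III 13019001. The others did not, among them I 10203001 (log2 change 1.38, limma adjusted p = 0.0859).

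Whether the hrde-1 effect differed between backgrounds was tested as an interaction. For hrde-1 with met-2 set-25, 0 bins were higher and 1 was lower than additive (limma, 2429 bins at an unadjusted p under 0.05). That bin, IV 2755001 to 2756000, read 12.3 RPKM in N2, 40.1 in hrde-1, 48.2 in met-2 set-25 and 4.20 in met-2 set-25 hrde-1 (limma adjusted p = 0.00654). For hrde-1 with set-32, 133 bins were higher and 21 lower than additive. In 111 of the 133, N2 stood above both single mutants, as at II 14602001 to 14603000 (36.7 RPKM in N2, 5.77 in hrde-1, 8.89 in set-32, 9.57 in set-32 hrde-1). At that bin met-2 set-25, of the same prefix as N2, was high too, at 39.6 RPKM. There set-32 met-2 set-25, met-2 set-25 hrde-1 and set-32 met-2 set-25 hrde-1 read 14.9, 7.27 and 25.45 RPKM. In 29 of the 133, set-32 hrde-1 stood above hrde-1 and N2, and Pol II in the met-2 set-25 hrde-1 background was higher with set-32 loss than without. The smallest p was at V 18121001 to 18122000, with 2.97 RPKM in N2, 4.55 in hrde-1, 2.31 in set-32, 70.5 in set-32 hrde-1, 24.4 in met-2 set-25 hrde-1 and 148 in set-32 met-2 set-25 hrde-1 (limma adjusted p = 3.95e-06). Centring left 8 higher and 3 lower bins and quantile normalization 0 and 0 (4797 at an unadjusted p under 0.05). The median interaction of the 133 bins was 2.03 as reported and 2.00 after quantile normalization, while its median SE grew from 0.43 to 0.51.

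For set-32 with met-2 set-25, 36 bins were higher and 216 lower than additive (limma). The top bin, III 4489001 to 4490000, read 16.2 RPKM in set-32 met-2 set-25 and 21.5 in set-32 met-2 set-25 hrde-1, against 78.9 in N2, 133 in set-32, 96.5 in met-2 set-25, 97.6 in hrde-1, 122 in set-32 hrde-1 and 158 in met-2 set-25 hrde-1 (limma adjusted p = 0.00495). The 2 low libraries are those with even coverage. Centring gave 59 higher and 1238 lower bins, and quantile normalization 7 and 26.

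The hrde-1 difference over GRTS bins was seen in each background. The median log2 difference was 2.47 against N2 (higher in 191 of 191 bins), 3.49 in the set-32 background (189 bins), 2.53 in met-2 set-25 (190 bins) and 1.81 in set-32 met-2 set-25 (188 bins), or 2.57, 3.39, 2.82 and 1.79 when centred. The set-32 and met-2 set-25 pairs each share a library prefix, so the difference holds within a prefix. As interactions, 8 GRTS bins were higher and 4 lower than additive for hrde-1 with set-32 (0 and 0 both when centred and after quantile normalization), and 0 and 0 for hrde-1 with met-2 set-25.

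Each mutant was also set against N2, with 1 library on each side and the N2 library shared by all 7 comparisons, so these differences compare libraries and have no replicate check. By the rule of size, hrde-1 had 875 higher and 913 lower bins and set-32 hrde-1 had 1212 and 1103. The figures were 1592 and 1288 for met-2 set-25 hrde-1 and 1938 and 1721 for set-32 met-2 set-25 hrde-1. Among strains with intact hrde-1, they were 511 and 1168 for set-32, 740 and 481 for met-2 set-25 and 1253 and 1470 for set-32 met-2 set-25. The marked bins differed between the groups: 181, 183, 179 and 172 of 191 GRTS bins were higher in the 4 hrde-1 mutants, and 3, 4 and 9 in set-32, met-2 set-25 and set-32 met-2 set-25. Of 215 GRH bins, 93, 86, 94 and 60 were higher in the same mutants, and 15, 4 and 10 in the others. The marks may rest on such libraries, so these counts are not independent evidence either. The median of all bins differed from N2 by -0.17 in set-32, 0.15 in met-2 set-25, 0.43 in set-32 met-2 set-25 and 0.37 in set-32 met-2 set-25 hrde-1. Centring therefore changed the splits, to 1096 higher and 696 lower for hrde-1, 2049 and 653 for set-32, 337 and 2327 for met-2 set-25, 291 and 12179 for set-32 met-2 set-25, 1802 and 634 for set-32 hrde-1, and 675 and 11806 for set-32 met-2 set-25 hrde-1.

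Highest against N2 in hrde-1, IV 14415001 to 14417000 was 55.4 against 2.57 RPKM, followed by IV 526001 to 529000 (60.2 against 3.25 RPKM) and IV 4123001 to 4137000 (87.8 against 6.71 RPKM). IV 913001 to 922000 was 110 RPKM in set-32 hrde-1 and 82.5 in met-2 set-25 hrde-1, against 4.29 in N2. In set-32 met-2 set-25 hrde-1, IV 16312001 to 16324000 was 70.3 against 3.04 RPKM, IV 909001 to 923000 was 109 against 4.68 RPKM and V 18118001 to 18124000 was 102 against 5.48 RPKM. II 2148001 to 2165000 followed in set-32 hrde-1 (73.8 against 5.29 RPKM), and II 9800001 to 9803000, with 0 GRTS bins, was 66.7 against 3.60 RPKM in met-2 set-25 hrde-1, ahead of IV 526001 to 529000 (64.5 against 3.25 RPKM). In set-32 the largest increases were single bins: IV 2510001 (15.2 against 3.24 RPKM), I 13614001 (56.7 against 14.6 RPKM) and IV 2647001 (68.4 against 19.1 RPKM). In met-2 set-25 they were IV 9591001, II 6806001 and III 9348001 (10.7 to 10.98 against 0.54 RPKM), and in set-32 met-2 set-25 I 12506001, I 10777001 and X 3566001 (10.1, 22.1 and 39.6 RPKM against 1.08, 3.51 and 7.02 RPKM).

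Among the largest decreases, III 5092001 to 5093000 recurred in hrde-1, set-32 hrde-1 and set-32 met-2 set-25 hrde-1 (7.69, 9.65 and 8.81 against 65.4 RPKM). III 1819001 to 1825000 recurred in hrde-1 and set-32 hrde-1 (3.64 and 5.42 against 31.4 RPKM), and IV 9563001 to 9565000 was 5.68 against 37.0 RPKM in hrde-1. The N2 library stands in each of these pairs, so part of such recurrence may come from it. V 3632001 to 3635000 was 6.88 against 64.7 RPKM in set-32 hrde-1. In set-32, X 10139001 to 10142000 was 2.64 against 26.8 RPKM, IV 9382001 was 1.15 against 16.3 RPKM and V 5700001 was 0.33 against 10.8 RPKM. II 10932001 to 10937000 was 11.6 against 119 RPKM in met-2 set-25, and V 3633001 to 3635000 was 16.4 against 89.4 RPKM in set-32 met-2 set-25. X 7229001 and X 1503001 to 1505000 were 2.73 and 9.77 against 23.8 and 78.9 RPKM in met-2 set-25 hrde-1, and V 18638001 to 18640000 was 16.02 against 135 RPKM in set-32 met-2 set-25 hrde-1. The regions III 13287001 and III 8376001 and the bin II 504001 made up the rest.

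To read the hrde-1 response in libraries that had not defined it, bins were listed in one pair of libraries and read in others. The first list held 1582 bins higher in met-2 set-25 hrde-1 than in met-2 set-25, 178 of them GRTS. These 2 libraries also differ in evenness (ratio of the 90th to the 10th percentile 12.21 and 7.63). Part of the list may follow evenness, which was not tested. The median log2 difference of the list from N2 was 0.62 in hrde-1, above all 10000 random lists matched on mean level (-0.01 to 0.08). It was 0.67 in set-32 hrde-1 (random lists -0.05 to 0.05). In set-32 it was 0.10, at the 79.2th percentile of random lists (0.03 to 0.13). With libraries centred the list was defined anew and grew to 3695 bins, so its readings mix another list with the centring. It read 0.49 in set-32 (random lists 0.33 to 0.40), 0.43 in hrde-1 (0.11 to 0.17) and 0.54 in set-32 hrde-1 (0.14 to 0.21). A list made with a log2 limit of 2 gave -0.11 in set-32 (random lists 0.03 to 0.24), 1.92 in hrde-1 and 2.39 in set-32 hrde-1, so the place of set-32 among random lists depends on these choices. The second list held 994 bins higher in set-32 hrde-1 than in set-32, 182 of them GRTS. Its median difference from N2 was 1.28 in met-2 set-25 hrde-1 (random lists -0.10 to 0.04). It was 0.10 in met-2 set-25 and 0.36 in set-32 met-2 set-25, above the random lists (-0.17 to -0.05 and -0.31 to -0.18). The median of all bins stood at 0.15 and 0.43 against N2, so the list was no higher than bins at large. Random lists were matched on the mean of all 8 libraries, which hrde-1 loss raises at listed bins, so their place shows no gain. The first list was matched in the same way, so the place of set-32 there shows no gain or loss either. Centred, the second list held 900 bins and read -0.21 and -0.13, again above the random lists (-0.49 to -0.37 and -0.85 to -0.72). Readings without N2, added after the data were seen, gave 0.38 for the first list in set-32 hrde-1 against set-32. The second gave 1.26 in met-2 set-25 hrde-1 against met-2 set-25. Defined anew at a pseudocount of 5 RPKM, the first list held 926 bins and read 0.89. Its centred version of 3695 bins read -0.084 (random lists -0.22 to -0.17).

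Autosome arms, known to be richer in H3K9me3 than centres, were compared with centres in each library. Mean log2 Pol II was lower on arms than in centres in all 8 libraries, from -0.22 in met-2 set-25 hrde-1 to -0.09 in set-32 met-2 set-25 hrde-1. Mutant minus other libraries was 0.02 for hrde-1, 0.03 for set-32 and 0.01 for met-2 set-25 (exact permutation p = 0.571, 0.314 and 0.8, adjusted 0.8 each, n = 4). Without set-32 met-2 set-25 hrde-1 the hrde-1 and met-2 set-25 differences turned to -0.0024 and -0.011.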

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

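Tests on even coverage, the left end of chromosome X and the block on chromosome I were chosen after the result was seen, as were the counts over other splits of the libraries, while the interaction tests were planned.

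For the named regions, the GRTS and GRH medians and the arm differences, the 4 libraries with and the 4 without each mutation were screened for a library far from the other 3. Of 128 such groups, 9 had one, where chance gives about 1 in 20. Values are log2(mean RPKM + 1). In set-32 met-2 set-25 hrde-1, V 17568001 to 17575000 was at 4.87 (other hrde-1 mutants 5.48 to 5.57) and II 13244001 to 13251000 at 5.001 (5.63 to 5.77). In met-2 set-25 hrde-1, III 5092001 was at 4.93 (other hrde-1 mutants 3.12 to 3.41) and I 4161001 at 2.47 (other met-2 set-25 mutants 2.97 to 3.06). X 32001 was at 2.66 in met-2 set-25 (other libraries with intact hrde-1 3.58 to 3.72). Among libraries with intact met-2 and set-25, V 20501001 to 20505000 was at 4.45 in set-32 hrde-1 (others 3.05 to 3.13) and IV 1825001 was listed at 0 in set-32 (others 1.46 to 1.66). In the same group I 4467001 was at 4.54 in N2 (others 4.85 to 4.90) and X 153001 to 161000 at 3.04 in hrde-1 (others 4.68 to 4.996).

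Effects differed between backgrounds in 154 bins for hrde-1 with set-32, 1 bin for hrde-1 with met-2 set-25 and 252 bins for set-32 with met-2 set-25 (limma interaction terms, Benjamini-Hochberg adjusted). With 1 library per genotype, such a bin can reflect 1 library as well as a genotype.

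Other splits of the 8 libraries into 4 and 4 were fitted in the same way where the model allowed, 33 with the real one. The real hrde-1 split called 932 bins and the highest other split 641, so 1 of 33 splits was as large, the smallest share possible. This does not exclude chance, because the count was chosen after the result was seen. The other splits were also fitted without the hrde-1 term, which adds to their residual spread and can lower their counts. For set-32, 22 of 33 splits called as many as the 1 bin of the real split, up to 1005, so chance cannot be excluded. For met-2 set-25, 4 of 33 splits called as many as the 445 bins of the real split, so chance cannot be excluded there either. One split called 33410 bins in place of met-2 set-25, which points to a structure of the samples. It set N2, met-2 set-25, set-32 met-2 set-25 and set-32 met-2 set-25 hrde-1 against the rest. The same split called the 641 bins in place of hrde-1, so its count depends on the factor it replaces. Its side with N2 holds 3 of the 4 met-2 set-25 libraries, both evenly covered ones among them. That side also holds the 4 libraries with the lowest ratios of the 90th to the 10th percentile (3.72 to 12.01, against 12.21 to 24.96 in the rest). The split thus follows the order of evenness, though N2 and met-2 set-25 hrde-1 lie close, and what drives it was not tested. Its other side holds 3 of the 4 hrde-1 mutants, so its 641 calls may include part of the hrde-1 effect.

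The met-2 set-25 calls may come in part from the even coverage of both libraries that also lack set-32. Without these 2 libraries 26 bins were called in place of 445, and 18 of them were shared with the original calls. Leaving out met-2 set-25 and met-2 set-25 hrde-1 in their place gave 50803 calls and a median shift of 0.66. Weak enrichment in those 2 libraries and a joint effect of set-32 with met-2 and set-25 remain open, since no other library carries these genotypes. The regions that kept their call without them, III 13287001, III 8376001, IV 5682001, V 20501001, V 20509001 and III 13019001, do not need these libraries. Absent DNA, which was not tested, would give the values at III 13287001 and III 8376001, so the calls there are not evidence of lower Pol II.

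Pol II over the first 210 kb of chromosome X was low in hrde-1, met-2 set-25 hrde-1 and set-32 met-2 set-25 hrde-1, by a median of -0.90, -1.05 and -1.44 on the log2 scale against N2, in 189, 182 and 194 of 209 bins, while met-2 set-25, with intact hrde-1, stood at -0.34 (145 bins lower) and the 3 other libraries at 0.04 to 0.16. Loss of hrde-1 alone stays open: set-32 hrde-1 differed from set-32 by only -0.039, where the other hrde-1 mutants differed from their matches by -0.90, -0.68 and -1.57, but 1 library does not exclude it. Even coverage is argued against in hrde-1 and met-2 set-25 hrde-1, whose ratios of the 90th to the 10th percentile were at least 1.017 times that of N2, but is left open in set-32 met-2 set-25 hrde-1, though the still more even set-32 met-2 set-25 library stood at 0.16. Fewer copies of the whole stretch would lower bins with little Pol II as much as the rest, but relative to bins of like level the 53 bins with the least Pol II stood at 0.819 ± 0.050 of N2 in hrde-1 and 0.824 ± 0.066 in met-2 set-25 hrde-1 (bootstrap SE over bins), against 0.553 ± 0.053 and 0.502 ± 0.053 in the 52 bins with the most. In set-32 met-2 set-25 hrde-1 these were 0.349 ± 0.029 and 0.505 ± 0.073, so fewer copies may hold there, while loss of part of the stretch and a strain difference beyond the named genes stay open.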

How the results depend on the processing

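Leaving out both evenly covered libraries, leaving out misanotated bins, and all alternatives for GRTS and GRH bins and for the list readings without N2 were chosen after the data were seen. The rise with hrde-1 loss held under all alternatives, with 675 to 897 higher bins and 685 to 982 with 1 library left out. Of the 932 calls, 687 were shared after quantile normalization, 678 with the prefix as a term and 771 without both evenly covered libraries. The lower bins (80) numbered 121 at a pseudocount of 5 RPKM, 16 at a mean of at least 5 RPKM, 38 centred, 15 after quantile normalization, 34 with the prefix and 23 to 435 with 1 library left out. For set-32, higher bins (0) numbered 1 at a pseudocount of 5 RPKM, 28 with the prefix and 0 to 37 with 1 library left out. Its lower bin (1) became 2 at a pseudocount of 5 RPKM and with the prefix, and 0 at a pseudocount of 0.5 RPKM, at a mean of at least 5 RPKM, after quantile normalization, without both evenly covered libraries and without misanotated bins, which removes that bin, with 0 to 57 when 1 library was left out. For met-2 set-25, higher and lower bins (318 and 127) were 206 and 63 at a pseudocount of 0.5 RPKM, 1625 and 649 at 5 RPKM, 50 and 10 at a mean of at least 5 RPKM, 41 and 6 after quantile normalization, 64 and 78 with the prefix, 19 and 7 without both evenly covered libraries, and 77 to 31040 and 30 to 7479 with 1 library left out. Centring gave 6828 lower bins. A lone sample left in an arm was assumed to vary like the others. Interactions of hrde-1 with set-32 (133 and 21) were 8 and 3 centred, 0 and 0 after quantile normalization and 214 and 35 at a pseudocount of 5 RPKM. Those of hrde-1 with met-2 set-25 (0 and 1) were 0 and 3, 0 and 0, and 2 and 14. Those of set-32 with met-2 set-25 (36 and 216) were 59 and 1238, 7 and 26, and 155 and 325. Against N2, the bins past the size rule are given in the order hrde-1, set-32, met-2 set-25, set-32 met-2 set-25, set-32 hrde-1, met-2 set-25 hrde-1 and set-32 met-2 set-25 hrde-1. As reported they were 1788, 1679, 1221, 2723, 2315, 2880 and 3659. At a pseudocount of 5 RPKM they were 1018, 798, 369, 1080, 1285, 1552 and 1829. With no minimum they were 4934, 10594, 8524, 21659, 5591, 5731 and 21224, at a minimum of 20 RPKM 979, 886, 302, 1587, 1373, 1610 and 2002, and at 3-fold 606, 353, 242, 349, 762, 882 and 877. Centring moved 4 of them, to 2702 for set-32, 2664 for met-2 set-25, 12470 for set-32 met-2 set-25 and 12481 for set-32 met-2 set-25 hrde-1. A log2 limit of 2 for the first list moved its reading to 1.92 in hrde-1, 2.39 in set-32 hrde-1 and 2.49 in set-32 hrde-1 against set-32, and turned set-32 to -0.11. A pseudocount of 5 RPKM also defined the lists anew (926 and 754 bins). It gave 0.89 in place of 0.38 in set-32 hrde-1 against set-32, and 0.052 and 0.062 in place of 0.10 for set-32 and, in the second list, met-2 set-25. Centring also defined the lists anew (3695 and 900 bins), so list and scaling changed together. Centred, set-32 read 0.49 in place of 0.10 for the first list, and set-32 hrde-1 against set-32 read -0.084. For the second list met-2 set-25 read -0.21 and set-32 met-2 set-25 -0.13. Centred random lists moved too, and all 4 readings lay above them. For hrde-1, centring gave GRTS bins 2.72 (adjusted exact p = 0.0571) and GRH bins 0.94 (0.0857), and leaving out both evenly covered libraries gave 2.90 and 1.01 (exact p = 0.1 each, the smallest that 3 against 3 allow). With 1 library left out they were 2.47 to 2.79 and 0.75 to 1.00 (adjusted exact p 0.0286 to 0.0571). GRTS and GRH bins turned to -0.0011 and -0.055 for set-32, and GRTS bins to -0.42 for met-2 set-25, when centred. With 1 library left out the set-32 values were -0.50 to 0.69 and -0.22 to 0.25, and the met-2 set-25 values -0.50 to 0.70 for GRTS and -0.56 to -0.13 for GRH bins, which stood at -0.84 centred (adjusted exact p = 0.229) and -0.15 after quantile normalization (1). Quantile normalization also gave GRTS bins 0.23 for set-32 and 0.0064 for met-2 set-25, and GRH bins 0.15 for set-32. Permutation within hrde-1 status left these differences as they were, with adjusted exact p of 0.833 for both lists and set-32, and 0.944 (GRTS) and 0.111 (GRH) for met-2 set-25. Arm minus centre differences ranged from -0.0024 to 0.042 for hrde-1, 0.0094 to 0.048 for set-32 (lowest adjusted exact p 0.0857, without set-32) and -0.011 to 0.034 for met-2 set-25. Over the named regions and bins, 814 pairs of a value and an alternative stayed the same, 103 lost their call, 35 gained one, 62 moved and 0 reversed. Where no reason is given, the cause was not tested. At 3.0 to 6.60 M reads, counting error limits single bins near 10 RPKM to 12.3 to 18.2%. Those foreseen for H3K9me3, for Pol II at bins rich in H3K9me3 and for the gene lists were not run. By replicate number, no paired analysis was possible because each genotype had 1 library and all carry the same number. Pairs of genotypes that differ in 1 factor are given as values in the results.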

Other observations

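The tests on the block of chromosome I were chosen after the result was seen, and the other regions of this part were picked after their values were seen, outside the rule fixed for named regions.

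Several short stretches of the left part of chromosome V stood higher in every met-2 set-25 carrier. V 2389001 to 2395000 was 9.64 ± 0.90 RPKM in the 4 carriers and 3.68 ± 0.30 RPKM in the others (SD, n = 4; limma adjusted p = 0.00744), and V 2498001 to 2503000 was 9.81 ± 1.16 against 3.67 ± 0.15 RPKM (limma adjusted p = 0.00586). Here met-2 set-25 hrde-1, a library without even coverage, read 8.92 and 9.40 RPKM and met-2 set-25 read 10.8 and 11.2 RPKM. V 2348001 to 2353000 and V 2456001 to 2461000 gave nearly equal values in every library (10.97 ± 2.08 and 11.2 ± 2.07 RPKM in carriers, 3.55 ± 1.00 and 3.65 ± 0.99 RPKM in the others), and 40.0% and 27.5% of them lay within 0.1 of a whole read, so they may share reads and their separate changes are uncertain. The longest region with higher Pol II in met-2 set-25 mutants, X 7366001 to 7387000, was 9.69 ± 3.28 against 2.78 ± 0.76 RPKM. III 10981001 to 10988000 was high in met-2 set-25 (23.3 RPKM) and met-2 set-25 hrde-1 (24.6 RPKM), while set-32 met-2 set-25 (8.67 RPKM) and set-32 met-2 set-25 hrde-1 (7.36 RPKM) were lower, against 6.12 RPKM in N2 and 3.11 to 3.65 RPKM in the 3 other libraries.

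A block of 16 misanotated bins on chromosome I, 10204001 to 10220000, was higher in every met-2 set-25 carrier: 3.21 times N2 in met-2 set-25, 4.65 in set-32 met-2 set-25, 2.12 in met-2 set-25 hrde-1 and 3.02 in set-32 met-2 set-25 hrde-1, against 0.613 to 0.961 in the 3 other mutants. Even coverage is argued against in met-2 set-25 hrde-1, whose ratio of the 90th to the 10th percentile was 1.017 times that of N2, and is left open in the 3 other carriers, where the block stood at least 1.37 times as high over N2 as other misanotated bins. Reads shared between near-identical copies are consistent with the values, of which 17.2% lay within 0.1 of a whole read, against 80.1% of values between 10 and 60 RPKM elsewhere. More copies of the block in these strains cannot be told apart from higher Pol II: the ratio to N2 varied over bins with an SD of at most 0.0896, below the counting error of 0.224, so the bins follow a common ratio, and with so few whole values they may not be separate measurements. Other misanotated bins stood at 1.43, 2.03, 0.847 and 2.20 times N2 in the same 4 libraries, and a gain of Pol II through loss of H3K9 methylation was not tested and stays open.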
